A study of Mus musculus with 2 samples.

How the data were processed

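Long-read RNA sequencing was applied to hippocampus of 2-month-old female B6CASTF1/J mice in 2 libraries of 1 group, numbered as biological replicates 1 and 2 in the labels. Each library has a table of read counts per transcript model and a set of model structures. The deposited values are whole-number counts of long reads per transcript model, with no normalization, and list only models with at least 1 read, as seen in the files. Per the text files deposited with them, they were derived from alignments to mm10, listed apart from the unfiltered alignments, with GENCODE M21 as the annotation. Per the file headers, the structure files name TALON as their source. The aligner, the sequencing platform and tool versions are not given in the sources used here. Unannotated models carry identifiers with the library's own name, so the libraries were processed separately, and other deposited values give the number of exons and the length of each model. The labels name ERCC and SIRV spike-ins, and of these the count tables held reads on ERCC only.

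Counts were summed per gene over all models that TALON gave to an annotated gene, by gene identifier, since 19 symbols belong to more than 1 identifier. Levels are counts per 1000000 reads not on spike-ins (CPM), with totals of 826596 reads in replicate 1 and 745492 in replicate 2. The confidence intervals of single-library shares are exact 95% Clopper-Pearson intervals, and the limit for a count of 0 is 3 counts of the total. Reads without molecular identifiers are not known to be independent molecules, so intervals and limits cover counting error only, and the chi-square, binomial and Fisher's tests, which take reads as independent, may give p-values that are too small. Gene coordinates and exon annotation were taken from GENCODE M21, the version the deposited files name, on mm10, 1-based. Single-exon models took 28.6% and 28.7% of non-spike-in reads, and 4.30% and 3.77% of these reads sat in models under 50 bases long, so the ends of such models are imprecise. How the authors' counting treats reads from near-identical copies or overlapping genes is not given in the sources used here. Haemoglobin, ribosomal protein and pseudogene counts are uncertain for that reason.

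Isoforms were compared between libraries by their chain of introns, since identifiers of unannotated models do not match. Full-splice reads are those of annotated models, of unannotated combinations of annotated splice sites, and of models with an unannotated splice site. Shares were computed for genes with at least 20 full-splice reads in each library, and a gene with more than 1 isoform had at least 2 with 10% or more in each library. Unannotated models in both libraries needed at least 5 reads in each. Unannotated single-exon models have no chain, and where they were counted they were pooled per gene and class.

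Library differences were tested per gene with a two-sided exact binomial test against the ratio of the totals, for genes with at least 20 reads together, at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold. Isoform shares were tested with two-sided Fisher's exact tests. The median log2 ratio of each list, with members of at least 10 reads together and 0.5 added to each count, was placed among 10000 random lists of the same size drawn from 20 bins of mean level. Such tests compare the 2 libraries, not conditions, and with 1 group no test between groups was possible. The design, the 35 gene lists, the rule for named genes and all alternatives but those named as chosen later were fixed before the data were examined. The rule takes the 15 nuclear genes with the highest mean, up to 4 leading members of each list with members at 0, the 20 isoform genes with the most reads, the 10 leading unannotated models and dominant unannotated isoforms, the 10 largest folds in each direction and the 5 smallest p-values for isoform shares. Some genes that this rule takes are not reported here.

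On simulated counts for the library comparison, with 200 of 9075 tested genes changed, the binomial test with its 2-fold limit recovered 44.0% of genes changed 2-fold, 82.0% at 3-fold, 98.0% at 4-fold and 100% at 8-fold, with 1 unchanged gene called. On simulated isoform counts for 4819 genes, 57.5% of 200 genes moved by 30 percentage points were recovered, with 6 unchanged genes called. Alternatives changed the read minimum, the fold, the pseudocount, the classes counted and the scaling (TMM from edgeR, factors 0.9997 and 1.0003), and left out each replicate in turn. Where classes were left out, CPM was taken over the reads of the classes kept, so genes that lost few reads rose. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and R 4.3.3 with edgeR 4.0.16, were used.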

Results

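Long-read RNA sequencing, in which one read can span a whole cDNA copy of a transcript, was carried out on tissue labelled as a layer of hippocampus from 2-month-old female mice of the B6CASTF1/J hybrid, the first-generation cross of C57BL/6J with CAST/EiJ. The series holds 1 group, hippocampus, with 2 libraries numbered as biological replicates 1 and 2, each started from 2 µg of RNA. The deposited tables hold 836240 reads in replicate 1 and 752291 in replicate 2, assigned to 135738 and 130247 transcript models. Spike-in RNAs of the ERCC mix took 9644 and 6799 of these reads. Levels are given as CPM, the reads of a gene per 1000000 reads not on spike-ins. One read was worth 1.21 CPM in replicate 1 and 1.34 CPM in replicate 2, and a count of 0 allows up to 3.63 and 4.02 CPM. With a single group no comparison between conditions was possible. The account therefore covers which genes and isoforms the hippocampus expressed, and how far the 2 libraries differed. The tests of gene levels, list shifts and isoform shares below set the reads of one library against those of the other. The labels do not state plainly that the replicates came from separate animals. The p-values set the difference between these 2 libraries against read-counting error only, and that difference may be technical.

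Apoe, the lipid carrier made mainly by astrocytes, stood at 4971 ± 315 CPM (mean ± SD, n = 2, as for all ± values here), then Ncdn (neurochondrin) at 3955 ± 23.2 CPM and the ubiquitin gene Ubb at 3909 ± 228 CPM. Gabarapl1, an autophagy protein, reached 3458 ± 511 CPM and Cpe, a peptide-processing carboxypeptidase, 3378 ± 148 CPM. Calm2 stood at 2942 ± 1.45 CPM, the ferritin heavy chain gene Fth1 at 2907 ± 2.01 CPM and the glycolytic enzyme Aldoa at 2706 ± 118 CPM. Ndrg4 (2199 ± 147 CPM) and Hpca, the hippocampal calcium sensor hippocalcin (2191 ± 38.9 CPM), came next. AC149090.1 on an unplaced contig (2041 ± 17.5 CPM), the calcineurin subunit Ppp3ca (1989 ± 184 CPM) and Cox4i1 of respiratory complex IV (1958 ± 535 CPM) were also among the 15 nuclear genes with the highest mean. Together the 15 genes held 4.71% of non-spike-in reads. At least 1 read in each library was found for 14787 annotated genes, 13066 of them protein-coding, and 1929 genes averaged 100 CPM or more.

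Neuronal markers were abundant throughout. All 15 pan-neuronal genes were detected in both libraries, with a median of 216 ± 4.997 CPM. Snap25, a protein of vesicle fusion, stood at 1651 ± 21.5 CPM, the neurofilament gene Nefl at 1415 ± 81.7 CPM, Syp at 1126 ± 76.2 CPM and Eno2 at 627 ± 31.6 CPM. Among 11 genes of excitatory neurons, Nrgn (neurogranin) reached 1754 ± 3.35 CPM, Camk2b 1299 ± 157 CPM, Rtn1 1197 ± 68.3 CPM and Slc17a7, the vesicular glutamate transporter of forebrain neurons, 1193 ± 16.4 CPM. Of 14 genes of inhibitory neurons, Cck (908 ± 66.0 CPM), Gad1 (285 ± 9.82 CPM) and Npy (118 ± 5.05 CPM) were among the 4 highest. Cck is also made by pyramidal cells.

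Genes used to tell the hippocampal fields apart were measured as well. In the list of dentate granule cells, Calb1 stood at 220 ± 35.9 CPM, C1ql2 at 153 ± 3.10 CPM, Lct at 59.7 ± 14.2 CPM and C1ql3 at 56.1 ± 13.0 CPM. The list of CA1 pyramidal cells was led by Wfs1 (254 ± 16.7 CPM), Mpped1 (163 ± 2.89 CPM), Pou3f1 (135 ± 3.62 CPM) and Fibcd1 (124 ± 9.98 CPM). For CA2 these were Pcp4 (285 ± 11.8 CPM), Amigo2 (48.1 ± 9.80 CPM), Rgs14 (23.7 ± 4.43 CPM) and Cacng5 (8.99 ± 2.46 CPM). For CA3 they were Homer3 (123 ± 4.47 CPM), Bok (111 ± 20.7 CPM), Nectin3 (41.3 ± 1.49 CPM) and Grik4 (30.9 ± 7.64 CPM).

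Glial and vascular cells were represented as well. Astrocyte genes had a list median of 279 ± 26.6 CPM (127.5 CPM without genomic models, 153.5 CPM with full-splice models alone), with Aldoc at 1499 ± 135 CPM, Sparcl1 at 1426 ± 147 CPM, the glutamate transporter Slc1a3 at 651 ± 34.9 CPM and the gap junction gene Gja1 at 533 ± 5.58 CPM. In oligodendrocytes, the myelin gene Mbp stood at 1708 ± 153 CPM, Trf at 418 ± 59.3 CPM and Cnp at 378 ± 4.19 CPM. The lowest genes of that list were Cldn11 (6.31 ± 1.34 CPM) and Mog (6.25 ± 3.14 CPM), and its median was 55.7 ± 0.0127 CPM. Oligodendrocyte precursor genes had a lower median of 20.9 ± 2.97 CPM. They were led by Pdgfra (36.3 ± 18.8 CPM), C1ql1 (31.9 ± 2.33 CPM), Tnr (28.1 ± 3.85 CPM) and Gpr17 (21.5 ± 3.83 CPM). Microglial genes had a median of 39.98 ± 6.07 CPM, with Csf1r (80.1 ± 15.7 CPM), C1qa (67.3 ± 2.28 CPM) and C1qc (51.8 ± 8.28 CPM) among the 4 highest. Endothelial genes were led by Bsg (771 ± 71.5 CPM), Cldn5 (200.04 ± 43.9 CPM), Itm2a (78.2 ± 0.590 CPM) and Pltp (70.3 ± 8.73 CPM). Their list median was 42.2 ± 11.3 CPM, and Pecam1 (8.93 ± 0.651 CPM) and Kdr (5.64 ± 2.29 CPM) were lowest. Mural cell genes were led by Rgs5 (60.8 ± 8.93 CPM) and Vtn (43.4 ± 3.16 CPM).

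**Figure D1:**
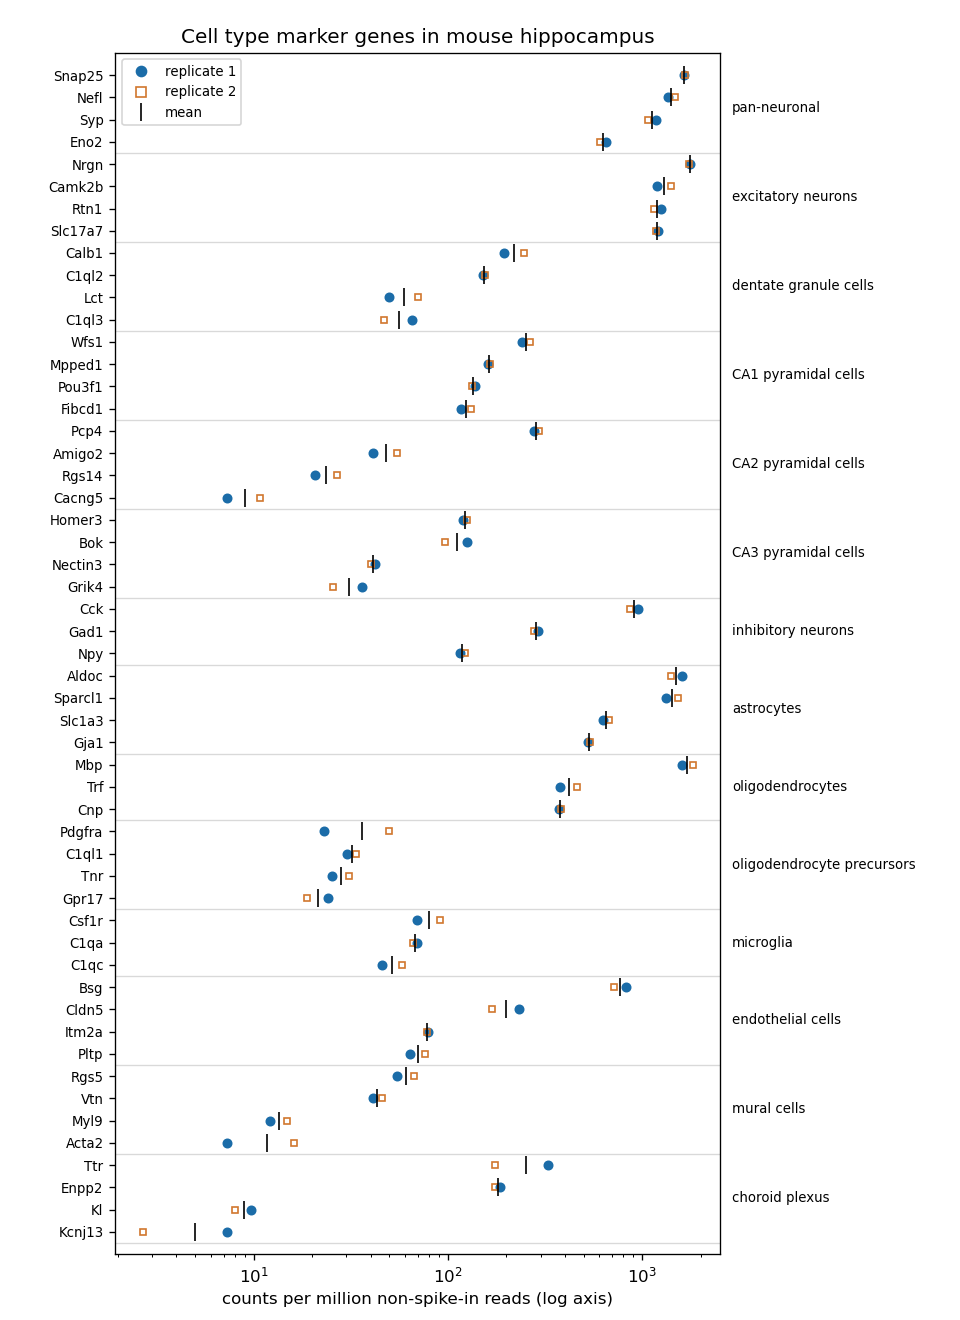
Levels of up to 4 of the highest members of 14 cell type lists, in CPM on a log axis, with replicate 1 as filled circles, replicate 2 as open squares and the mean as a bar. Nrgn (1754 CPM) and Mbp (1708 CPM) are the highest of the genes drawn, and Ttr differs between the libraries (271 reads against 131).

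Markers of neighbouring tissue were mostly low. Ttr, the transthyretin gene of choroid plexus, had 271 and 131 reads (252 ± 108 CPM) and Enpp2 180.4 ± 6.63 CPM, but 10 of the 12 choroid plexus genes lay under 10 CPM, and Aqp1 and Otx2 had no read. Ependymal genes were led by Rsph1 at 19.4 ± 8.61 CPM, with 5 of 6 members under 10 CPM. Genes of fibroblasts and meninges were led by Dcn (35.5 ± 19.9 CPM). For thalamus, Prkcd (32.8 ± 10.5 CPM) and Rora (28.3 ± 7.83 CPM) led, for cortex Fezf2 (39.5 ± 2.89 CPM) and Lamp5 (31.5 ± 8.59 CPM), and for striatum Ppp1r1b (57.1 ± 3.03 CPM) and Penk (39.1 ± 7.94 CPM). The haemoglobin genes Hba-a1 (192 ± 52.7 CPM), Hbb-bs (81.8 ± 28.5 CPM), Hba-a2 (58.1 ± 41.1 CPM) and Hbb-bt (16.3 ± 11.1 CPM) were detected in both libraries. Hba-a1 and Hba-a2 are near-identical, so the split of reads between them is uncertain. Of 4 genes on the Y chromosome, Kdm5d had 1 read and Ddx3y, Uty and Eif2s3y none, in animals labelled female.

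Synaptic genes covered the glutamate and GABA systems. Of 16 genes of vesicle release, 15 reached 100 CPM, led after Snap25 by Vamp2 (1234 ± 97.1 CPM), Syp and Rab3a (1063 ± 12.4 CPM). Pclo, a very long transcript, had 12 and 13 reads. AMPA receptor subunits were led by Gria1 (587 ± 15.8 CPM) and Gria2 (505 ± 22.4 CPM), followed by the kainate subunit Grik5 (134 ± 7.97 CPM) and Gria3 (64.0 ± 10.1 CPM). Grin1, the obligatory NMDA receptor subunit, stood at 583 ± 38.5 CPM, against 82.0 ± 16.8 CPM for Grin2b, 51.0 ± 1.92 CPM for Grin2c and 43.7 ± 4.91 CPM for Grin2a. How fully RNAs of different length were recovered was not measured, so such differences between genes may not reflect RNA amounts. Metabotropic receptors were low, led by Grm5 (49.9 ± 9.04 CPM), and Grm6 had no read. Of 13 GABA-A subunits, 4 averaged 100 CPM or more, among them Gabra5 (254 ± 18.5 CPM). Among 18 postsynaptic scaffold genes, Dlgap1 (294 ± 26.0 CPM), Dlgap3 (223 ± 15.2 CPM), Dlgap4 (199 ± 16.3 CPM) and Dlg3 (176 ± 9.24 CPM) were highest. Immediate early genes were led by Junb (125 ± 0.755 CPM), Homer1 (103 ± 11.1 CPM), Egr3 (81.5 ± 2.35 CPM) and Egr4 (67.1 ± 7.59 CPM). The Homer1 level covers all its isoforms. Of its full-splice reads the long Homer1-203 held 71.0% ± 2.64 and the short Homer1-204 18.9% ± 6.54. Fos had 2 and 7 reads, Npas4 3 and 0, and Fosb none. The levels of these receptor and scaffold genes depended on the models counted, by an amount that differed between lists. The AMPA and kainate list median was 36.6 CPM, 38.9 CPM without genomic models and 27.8 CPM with full-splice models alone. For GABA-A receptors these medians were 49.5, 43.7 and 40.4 CPM. Without genomic models and with full-splice models alone, the list median went from 43.7 CPM to 22.7 and 10.6 CPM for NMDA receptors, from 18.6 to 10.6 and 2.87 CPM for metabotropic receptors and from 83.7 to 40.9 and 24.8 CPM for scaffold genes.

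Genes tied to neurodegeneration were all detected in both libraries. After Apoe, the prion protein gene Prnp stood at 1402 ± 20.97 CPM, App at 988 ± 48.5 CPM and Clu at 494 ± 21.5 CPM. Imprinted genes were led by Gnas (1276 ± 46.3 CPM), Snrpn (1058 ± 18.2 CPM), Meg3 (478 ± 0.231 CPM) and Ndn (301 ± 41.9 CPM), while H19 and Peg10 had no read. Long noncoding RNAs were led by Meg3, Snhg11 (226 ± 4.23 CPM), Miat (171 ± 14.3 CPM) and Malat1 (147 ± 32.4 CPM), and Rmst had no read. Mitochondrially encoded RNAs were led by mt-Co1 (394 ± 17.1 CPM), mt-Rnr2 (341 ± 37.5 CPM), mt-Rnr1 (241 ± 25.6 CPM) and mt-Cytb (202 ± 3.97 CPM). Nuclear genes of oxidative phosphorylation had a median of 199 ± 7.98 CPM, led by Ndufa4 (1470 ± 88.9 CPM), Atp5b (1449 ± 59.8 CPM), Cox8a (950 ± 70.1 CPM) and Atp5a1 (862 ± 1.84 CPM). Ribosomal protein genes had a median of 108 ± 10.1 CPM, with Rpl41 (588 ± 53.4 CPM), Rpl3 (568 ± 43.1 CPM) and Rpl5 (478 ± 18.7 CPM) among the 4 highest. No read was found for Rpl10l, Rpl32l, Rpl39l, Rpl6l and Rps3a3, nor for Cox6b2, Cox6c2, Cox7b2 and Cox8c of the respiratory list. Of all 35 lists, 30 had a median member at 10 CPM or above. Without genomic models the list median also fell from 124 to 68.5 CPM for CA1 pyramidal cells, from 20.9 to 8.43 CPM for oligodendrocyte precursors, from 24.2 to 7.62 CPM for imprinted genes and from 33.6 to 14.6 CPM for long noncoding RNAs. With full-splice models alone it fell from 33.8 to 22.1 CPM for dentate granule cells and rose from 58.1 to 87.2 CPM for blood and from 102 to 156 CPM for the mitochondrial genome. Levels in both alternatives were scaled to the smaller total of reads kept, so a rise does not mean more reads.

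The reads were sorted by the deposited transcript class. Models with the splice structure of an annotated transcript held 56.0% ± 0.560 of all reads, spike-ins included (56.4% in replicate 1, exact 95% Clopper-Pearson interval 56.3 to 56.5%, and 55.6% in replicate 2, 55.5 to 55.7%). Models that join annotated splice sites in an unannotated combination held 6.23% ± 0.0492 and models with an unannotated splice site 3.58% ± 0.0795. These 3 classes, called full-splice here, held 65.8% ± 0.530. Incomplete splice matches, which carry part of an annotated chain of introns, held 10.5% ± 0.390, and 68.6% ± 0.0669 of them kept the 3' part of the chain, against 7.75% ± 0.539 that kept the 5' part. Genomic models, mostly unspliced reads that overlap a gene, held 9.07% ± 0.113. Antisense models held 12.9% ± 0.385 and intergenic models 1.79% ± 0.131. Of the antisense reads 98.5% ± 0.156 had a single exon.

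**Figure D2:**
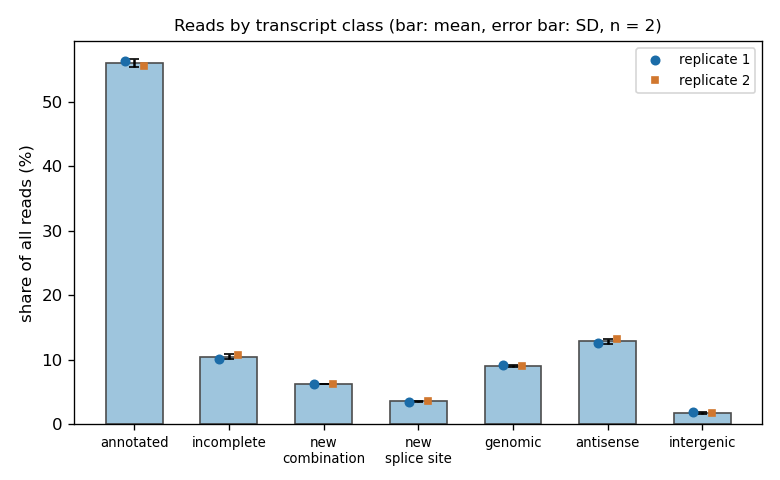
Share of all reads in each transcript class, with bars for the mean, error bars for the SD (n = 2) and points for the 2 libraries. Annotated structures hold 56.0% and antisense models 12.9%.

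Isoform shares were measured among full-splice reads, with models joined across libraries by their chain of introns. In 4819 genes with at least 20 such reads in each library, the dominant isoform held a median of 84.2% of the gene's reads (quartiles 62.4 and 94.5%), and the dominant chain was the same one in both libraries for 4580 genes. At least 2 isoforms, each with 10% or more in each library, were found in 1445 genes (29.99%). Of the 57 genes fixed for isoform analysis, 46 had enough reads. The dominant isoform was an annotated one in 38 of the 46, held at least 90% in 6 and under 50% in 13. Genes among the 20 of them with the most reads are described below, with coordinates on mm10.

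Pairs of mutually exclusive coding exons set apart the isoforms of several of these genes. In Snap25, Snap25-201 held 90.5% ± 0.215 and Snap25-202 6.47% ± 0.0821, and they differed by 118-base coding exons at chromosome 2, 136770057 to 136770174 in the first and 136769743 to 136769860 in the second. In the pyruvate kinase gene Pkm, Pkm-202, with the coding exon at chromosome 9, 59675029 to 59675195, held 88.5% ± 0.658. Pkm-201, with the exon at 59675568 to 59675734, held 9.02% ± 0.706. The AMPA receptor genes carry the exon pair known as flip and flop, each 115 bases long. In Gria1 the model with the exon at chromosome 11, 57309769 to 57309883, held 68.9% ± 0.190, and that with 57310608 to 57310722 held 20.2% ± 0.297. In Gria2 the model with the exon at chromosome 3, 80691320 to 80691434, held 56.7% ± 1.30, and that with 80690404 to 80690518 held 26.6% ± 1.15.

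Single coding exons were skipped or kept in others. App-201, which lacks the 168-base exon of the Kunitz protease inhibitor domain at chromosome 16, 85043576 to 85043743, held 88.6% ± 2.78, and App-202, which keeps that exon, 4.81% ± 1.63. In Ppp3ca the model with a 30-base coding exon (chromosome 3, 136932011 to 136932040) held 59.1% ± 3.71 and the model without it 36.3% ± 3.52. Grin1 was the most divided of these 20. Grin1-201, with a 111-base coding exon at chromosome 2, 25294438 to 25294548, held 29.8% ± 3.40 and Grin1-205, without it and with another acceptor for the next exon, 22.1% ± 2.85. In Mbp the model without a 123-base coding exon (chromosome 18, 82578936 to 82579058) held 67.9% ± 1.76 and a model with it 13.5% ± 0.397. In Camk2b, Camk2b-209 held 72.8% ± 1.46, and an unannotated combination without the 45-base coding exon at chromosome 11, 5981070 to 5981114, held 8.96% ± 0.634.

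Different first or last exons, or added exons, set apart another group. Rtn1-201, starting at a 196-base exon (chromosome 12, 72236529 to 72236724), held 56.4% ± 2.28, and the longer Rtn1-202, which starts at 72408311 to 72409054, 42.1% ± 2.36. Syn2-205, which ends earlier, held 63.6% ± 0.422 and Syn2-201, with 2 more coding exons, 33.6% ± 0.634. Rtn3-203 held 77.9% ± 1.65 and Rtn3-202, with 2 further coding exons of 2124 and 57 bases (chromosome 19, 7456300 to 7458423 and 7467811 to 7467867), 11.8% ± 0.598. Gfap-201 held 89.0% ± 2.74, and Gfap-202, with another last exon, 4.80% ± 0.131. Ywhaz-204 held 82.8% ± 2.71 and Ywhaz-201, with a further untranslated or noncoding exon, 10.1% ± 1.45. Gnas-208 held 93.1% ± 1.03, Apoe-206 97.1% ± 0.589 and Aldoa-201 96.4% ± 0.0763. Calm2-201 held 98.5% ± 0.0186.

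**Figure D3:**
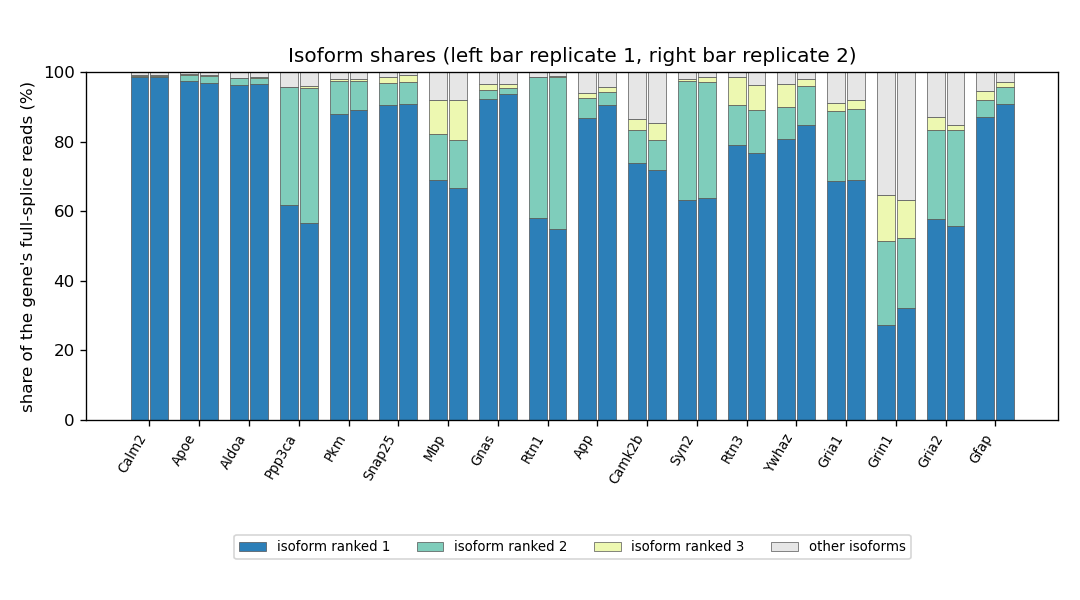
Share of each gene's full-splice reads held by its 3 most abundant isoforms, in percent, for 18 of the 20 genes with the most reads among those fixed for isoform analysis, with replicate 1 as the left bar and replicate 2 as the right bar of each pair. Calm2 is nearly all one isoform (98.5%), and in Grin1 the leading isoform holds 29.8%.

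Among the other genes of that list, a few were chosen for mention after their values were seen. Cdc42 was split between Cdc42-201 (49.2% ± 1.11) and Cdc42-202 (45.5% ± 0.261), which have different last exons. The longer clathrin light chain isoforms led in both genes. Clta-205, with coding exons of 54 and 36 bases that the next model lacks, held 63.2% ± 3.29, and Cltb-201, with 1 such exon of 54 bases, 76.2% ± 0.643. In Homer1, the long Homer1-203 held 71.0% ± 2.64 and the short Homer1-204 18.9% ± 6.54.

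Unannotated models that recur in both libraries were led by a structure of Nrgn. The chain match gave 1318 such models with at least 5 reads in each library, in 975 genes. Of these 1047 were unannotated combinations and 271 used an unannotated splice site. The Nrgn model (chromosome 9, 37544492 to 37552904, 3 exons) had 1343 and 1220 reads, 98.1% ± 0.391 of the gene's full-splice reads. Its intron at 37545349 to 37545947 is not in the annotation used. Oaz1, the ornithine decarboxylase antizyme, had 612 and 528 reads in an unannotated combination (chromosome 10, 80826656 to 80829290), 96.2% ± 0.657 of the gene. Cpne6 had 620 and 461 reads (47.1% ± 0.490), Apbb1 328 and 281 (63.4% ± 0.830), Oaz2 225 and 192 (92.3% ± 0.648), Ctbp1 195 and 182 (57.0% ± 0.270), Sept7 195 and 178 (89.2% ± 2.13) and Pls3 203 and 167 (79.9% ± 2.70). Among models with an unannotated splice site, the most read was one of Pitpna (248 and 233 reads, 97.95% ± 0.653), with the intron at chromosome 11, 75603485 to 75609104. One of Rab3a followed (227 and 192 reads, 28.0% ± 0.555), whose intron at chromosome 8, 70754870 to 70755855, starts 1 base from an annotated start. Most unannotated chains were seen in one library alone: 10605 of 71077 had a read in both.

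An unannotated isoform was the dominant one in both libraries in 268 genes, 5.56% of the 4819. The chain was the same in both libraries in 232 of these, with 189 unannotated combinations and 43 unannotated splice sites. The 10 with the most full-splice reads were Nrgn, Cpne6, Oaz1, Apbb1, 2010300C02Rik, Hnrnpk, Ctbp1, Sept3, Sh3glb2 and Pitpna. In Cpne6 the annotated Cpne6-201 held 28.1% ± 0.813 and differed by the end of 1 intron (chromosome 14, 55511957 against 55511980). In Ctbp1 the annotated Ctbp1-201 held 18.8% ± 1.43 and lacked a 193-base coding exon at chromosome 5, 33269442 to 33269634. The dominant isoform held 53.1% ± 0.191 in Sept3, 39.8% ± 3.29 in Sh3glb2, 38.4% ± 1.42 in the splicing regulator Hnrnpk and 38.2% ± 1.80 in 2010300C02Rik. With at least 50 reads in each library the count was 117 genes. With all models of a gene counted it was 1027, but incomplete and genomic models then enter by construction (215 and 410 genes taken alone, against 217 and 47 for unannotated combinations and splice sites).

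Gene levels in the libraries were close. Across 18497 genes with a read in either library, log2(CPM + 1) had a Pearson correlation of 0.931 and a Spearman correlation of 0.933. These are across genes, which are not independent replicates. The counts of 9062 genes with at least 20 reads differed by more than the sampling noise of independent reads (chi-square 12641 on 9061 degrees of freedom, a ratio of 1.40). Duplicate reads, which cannot be told apart without molecular identifiers, and assignment of reads made separately in each library may add to this ratio, which was 1.36 after merging overlapping genes, a test chosen after the data were seen. A two-sided exact binomial test per gene called 28 of 9062 genes at a Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold, 13 higher in replicate 1 and 15 higher in replicate 2. Leaving out genomic models raised the count to 61. Merging genes whose models overlap on one strand, an alternative chosen after the data were seen, lowered it to 13.

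Some of the calls came as pairs of nearby genes on the same strand that differed in opposite directions. Ccdc159 (chromosome 9, 21927471 to 21935872) had 184 reads in replicate 1 and 2 in replicate 2 (adjusted p = 2.93e-44, exact binomial test), while its neighbour Plppr2, which encodes a phospholipid phosphatase-related protein, had 152 and 343 (adjusted p = 1.85e-19, exact binomial test). Nlgn2, the neuroligin of inhibitory synapses, had 99 reads and 1 read (adjusted p = 2.70e-23, exact binomial test) and the adjacent Spem1 0 and 74 (adjusted p = 1.90e-21, exact binomial test). Tcte1 had 96 and 0 reads (adjusted p = 9.18e-24, exact binomial test). Also among the 10 genes with the largest fold toward replicate 1 were Gm49247 (20 and 0 reads), Rtl1 (24 and 1), Gm3448 (24 and 3), Gprasp2 (85 and 18) and Pgk1-rs7 (36 and 8). Toward replicate 2 they were E030018B13Rik (0 and 20), the processed pseudogene Vcp-rs (2 and 43), Nuak1 (1 and 19), Ap1g2 (6 and 80), Gm26848 (8 and 36), Gm42742 (24 and 81), Kcna1 (14 and 41), Hba-a2 (24 and 65) and Pum2 (16 and 41). An intron chain found in both libraries was assigned to another annotated gene in 139 of 37614 cases, and in 4 of the 28 called genes such chains held at least 50% of the reads of the higher library.

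**Figure D4:**
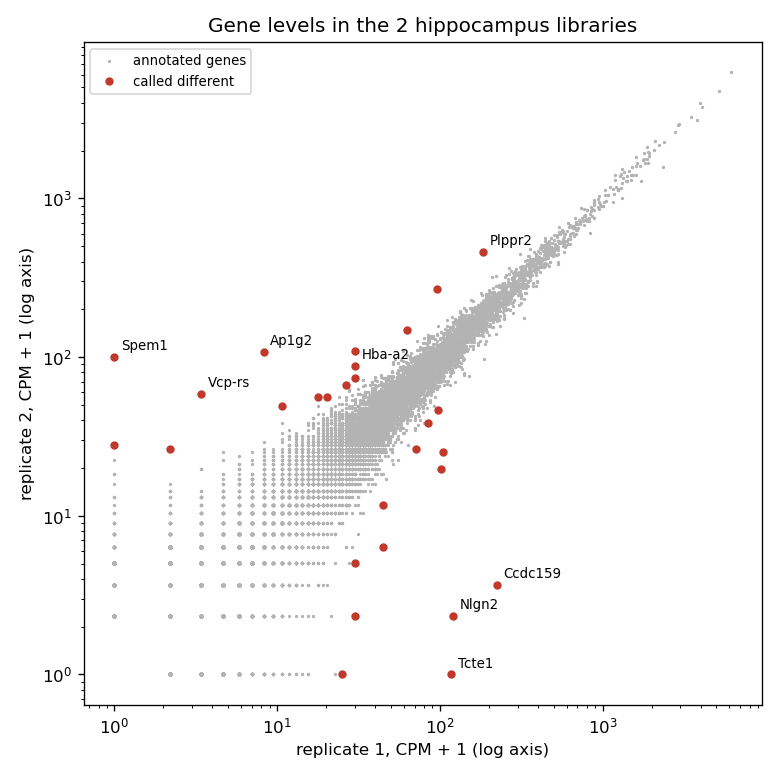
CPM + 1 of each annotated gene in replicate 1 (horizontal) and replicate 2 (vertical), both on log axes, with the 28 called genes in red. Most genes lie along the diagonal, and Tcte1, Nlgn2, Ccdc159 and Spem1 lie far from it.

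Blood genes showed the largest list shift between the libraries. The median log2 ratio of replicate 2 to replicate 1 for 4 haemoglobin genes was 1.09, at percentile 100 of 10000 random lists matched on mean level, and all 4 were higher in replicate 2. Microglial genes (median 0.34, percentile 98.9, 10 of 12 higher in replicate 2) and astrocyte genes (0.15, percentile 97.9, 10 of 13) also lay above the middle 95% of the random lists. Genes of fibroblasts and meninges lay below it (−0.65, percentile 1.24, 5 of 5 lower in replicate 2), as did ribosomal protein genes (−0.09, percentile 0.31, 50 of 78 lower) and nuclear oxidative phosphorylation genes (−0.09, percentile 0.12, 52 of 71 lower). In all, 6 of 33 lists lay outside that range, where 1.65 would be expected if the members of each list varied independently. The random lists draw genes independently, while members of a list can vary together and some lists share members. Whether 6 is more than chance gives cannot be judged from this. The choroid plexus list, with 3 members measured, stayed inside it (−0.24, percentile 9.38), as did all neuronal and synaptic lists. These percentiles describe these 2 libraries.

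Isoform shares differed between the libraries in 9 of 4819 genes (two-sided Fisher's exact test of the dominant isoform against the rest, Benjamini-Hochberg adjusted p under 0.05). The smallest p belonged to Camta2, a calmodulin-binding transcription activator, where a 22-exon model held 184 of 289 full-splice reads in replicate 1 and 0 of 107 in replicate 2 (adjusted p = 1.17e-33, Fisher's exact test). Aplp2, related to App, followed with 241 of 358 and 0 of 91, and Dctn1 (dynactin) with 0 of 61 and 92 of 163 (adjusted p = 7.93e-15, Fisher's exact test). In these 3 genes the same intron chain was present in both libraries (184 and 142 reads in Camta2, 241 and 218 in Aplp2, 112 and 92 in Dctn1) but was filed as full-splice in one and as incomplete in the other. Rhbdl1-201 held 40.5% (32 of 79) and 93.8% (30 of 32), and Stub1-201 91.0% (131 of 144) and 68.0% (102 of 150). With each chain given 1 class in both libraries, an alternative chosen after the data were seen, 4 genes were called: Rhbdl1, Stub1, Bhlhb9 and Plppr2. With intron chains instead given the gene of replicate 1 in both libraries, and classes left as deposited, 3 genes were called. The class differences of Camta2, Aplp2 and Dctn1 remained there, so the genes called need not be among the 4 named. Chains assigned to different genes in the 2 libraries tied Plppr2 to Ccdc159 and Bhlhb9 to Gprasp2. Rhbdl1 and Stub1 lie near each other on chromosome 17 (25834465 to 25837295 and 25830505 to 25833361). Assignment to neighbouring genes was therefore not excluded for these 4.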

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

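The test of antisense reads on the spike-ins was chosen after the result was seen. Antisense and intergenic models belong to no comparison above and are given for that reason. Intergenic models held 1.79% of all reads.

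Antisense models held 12.9% of all reads, led by a mean of 12968 reads opposite Gm26917 on chromosome 17, which had 10 and 21 sense reads. Of its 12091 and 13844 antisense reads, 12080 and 13838 belonged to a locus with its 3' end at 39843013. No T-rich stretch was found there, and what RNA these reads come from was not examined. Cplx2, a synaptic complexin with 331 and 290 sense reads, followed with a mean of 3566 antisense reads. A general rate of wrong strand calls was argued against by the ERCC spike-ins, where 0.734% of reads were antisense, against 48.9% ± 0.830 of the single-exon reads in annotated genes or antisense loci. Priming at A-rich stretches of first-strand cDNA, which mirror T-rich stretches of the sense RNA, could account for part: 45.5% of the antisense 3' ends searched had such a T-rich stretch within 30 bases, against 13.8% at positions moved 200 bases. The search covered 511 and 466 loci (43633 and 41049 reads) and left out 961 and 855, and ends with a T-rich stretch held 23.8% and 30.7% of the reads searched, so most antisense reads stay open. No biological explanation was tested.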

How the results depend on the processing

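The alternatives that merged genes by the overlap of their models or annotation, gave chains the gene of replicate 1 or gave each chain 1 class were chosen after the data were seen. Among multi-exon models alone, annotated models held 73.9% of reads, incomplete matches 11.6%, unannotated combinations 8.83%, unannotated splice sites 5.07%, genomic 0.248%, antisense 0.274% and intergenic 0.0572%, as leaving out single-exon models removes most of the last 3 classes by construction. Without spike-ins the unannotated combinations held 6.30%. The Pearson correlation was 0.792 with a pseudocount of 0.1 and 0.941 for genes with at least 10 reads. Genes differing between libraries numbered 61 without genomic models and 13 with genes merged by overlapping models, and from 21 to 35 under the other alternatives. Genes with at least 2 isoforms numbered 626 at a 20% share, 649 at 50 reads and 939 with annotated models alone. The median dominant share was 98.2% with annotated models alone, 65.4% with all models and 88.3% at 50 reads. Unannotated dominant isoforms numbered 117 at 50 reads. With all models 1027 genes were counted, as incomplete and genomic models enter by construction. Unannotated models in both libraries numbered 10605 at 1 read, 575 at 10 reads and 0 by deposited identifier, since these identifiers are made per library. Isoform shares differed in 75 genes with all models, 3 with the gene of replicate 1 and 4 with 1 class per chain. With one replicate left out the ranges were 55.6 to 56.4% for annotated models, 12.6 to 13.2% for antisense models, 16506 to 16778 genes detected, 1952 to 2107 genes with at least 2 isoforms, 83.3 to 83.8% for the dominant share and 344 to 374 unannotated dominant isoforms. The gene and isoform counts then needed their limits met in 1 library instead of both, so they exceed the main counts by construction. List medians moved by more than their spread in 18 of 35 lists without genomic models, in 25 with full-splice models alone and in none with TMM scaling. Leaving out classes also lowers the total that CPM is scaled to, which raises medians by construction. Where no construction is named, the cause was not tested.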

Other observations

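The tests of explanations for the differences between the libraries were chosen after the result was seen, while the counts of 28 genes and 9 genes they start from were planned. Opposite Shank1, a scaffold protein of excitatory synapses, 2431 and 2028 antisense reads were counted against 66 and 61 sense reads, and opposite the glutamate transporter Slc1a2 1839 and 1510 against 215 and 222. Actb, in contrast, had 287 and 292 antisense reads against 593 and 547 sense reads. These genes were chosen after their values were seen.

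Incomplete splice matches were tested against transcript length. Across 6806 genes, the share of reads that kept the 3' part of the chain rose with the length of the gene's most read annotated model (Spearman 0.332, and 0.314 and 0.326 in the single libraries), from 7.35% of reads in the shortest of 4 length classes to 18.5% in the longest. Reads that stop short of the 5' end of long RNAs may therefore account for part of this class. Genes are not independent replicates, and no biological explanation was tested.

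The differences between the libraries may lie partly in how reads were assigned. With one class given to each intron chain in both libraries, the genes with differing isoform shares fell from 9 to 4, with Camta2, Aplp2, Dctn1 and Smarca2 no longer called. Gpr162 was no longer called either. Its dominant chain had 79 and 67 reads both in its own class and over all classes, so a class change of that chain does not account for its loss. Merging genes that overlap on the same strand left 21 of 28 gene calls when done by annotation, and gave a count of 13 when done by their models, which leaves open how many calls come from assignment to neighbouring genes. No biological explanation was tested.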
